A study of Mus musculus with 48 samples.

How the data were processed

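RNA was measured in fibroblast lines from littermate mouse embryos of embryonic day 14.5, with Zfp36 (WT, Zfp36 +/+) or with Zfp36 disrupted (KO, Zfp36 -/-), by the labels apparently 1 line of each. Per the labels' protocols, cells were held in 0.5% serum for 16 h and given 10% serum for 90 min, and actinomycin D, an inhibitor of transcription, was then added. Samples were taken at 0, 30, 60, 90 and 120 min of actinomycin D, each from 3 combined dishes of 100 mm. The dose of actinomycin D is given as 5 ug/ml in the series text and 0.5 ug/ml in the sample names, and the sources used here do not settle which was used. The experiment was run 5 times on different days, with both lines side by side, and the replicate number names the experiment. Samples of serum-deprived cells, which the series text mentions, are not analysed here. The 10 groups of line and time hold 5 arrays each, except KO at 0 min (4 arrays, no replicate 5) and KO at 60 min (4 arrays, no replicate 4), 48 arrays in all.

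Per the labels' protocols, 1 ug of total RNA was amplified, 15 ug of biotin-labelled cRNA was hybridised for 16 h to Affymetrix Mouse Genome 430 2.0 arrays, and the arrays were processed on a Fluidics Station FS450, scanned on a Scanner 3000 and read with GeneChip Operating Software 1.2.0.037. The deposited values are log2 signals, given per probe set and array. How the authors summarised the probes, corrected the background and normalised the arrays is not given in the sources used here, and the log base was inferred from the range of the values, up to 13.43. The array medians lay between 8.47 and 8.56, so the deposited scaling was kept. The 5th percentile of each array lay between 8.02 and 8.13 and the 95th between 10.34 and 10.50, so that values near 8 carry little or no signal and a fall that ends there is compressed. The number of arrays limits the precision. Where a group mean lay at or under 8.13, the highest 5th percentile, a fold was computed against that value and given as at least so high, or left out. Lower limits on signal are not given, because the deposited files hold no detection calls.

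Of the 45101 probe sets, 64 control probe sets were left out, and the 27500 with a value above the array's median in at least 4 arrays were tested. Of these, 23140 carry 1 gene symbol in the platform annotation, 681 several and 3679 none, and the first group covers 13018 genes. Symbols of 23064 of them were found in the gene annotation of the GRCm38.p6 assembly, and 0 symbols changed. That annotation was also used for the chromosome of a gene and for which genes neighbour each other. Where 1 value per gene was needed, the probe set with the highest mean over all arrays was taken.

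Fits used limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8), with an intensity trend and robust empirical Bayes, over all 48 arrays. Slopes were fitted as straight lines of log2 signal on time in hours, with an intercept and a slope per line, and the difference of the slopes (KO minus WT, log2 per h) was the main test. A probe set was called slower in KO where this difference lay above 0 and the WT slope below 0, both past the threshold, and faster in KO where the difference lay below 0 and the KO slope below 0, both past the threshold. Changes over 120 min in each line and the differences between the lines at 0 and 120 min came from a fit with 1 mean per group. Each test was two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over the probe sets tested. Values are relative to the array average, so a rise after actinomycin D can be a smaller fall than the average and need not be new RNA. Whether transcription was fully stopped was not tested. Errors of slopes and differences are standard errors (SE) from the fit, and errors of group means are SD over arrays.

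Gene lists were tested with limma's camera (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation. Counts adjusted over a list alone use p-values adjusted within that list. For slopes these counts ask only for the sign of the difference and not for a fall in WT or KO past the threshold. The test by fry asks whether the genes of a list move on balance in 1 direction, and does not compare them with other genes. The 21 lists were: the TTP family; reported TTP targets; immediate-early transcription factors; cytokines, chemokines and growth factors; MAP kinase and receptor feedback; NF-kappaB feedback and targets; serum response and matricellular; p53 targets and growth arrest; mRNA decay factors; ribosomal proteins; glycolysis; fibroblast matrix and stroma; interferon-stimulated; cell cycle; epithelial, muscle, endothelial, macrophage and blood, neural, and cartilage and bone markers; and sex-linked genes. Named genes were Zfp36 and Ier3, which the study followed up on these samples; the 16 genes with the highest slope difference among those called slower and the 8 with the lowest among those called faster; the 8 highest and 8 lowest past the threshold at 0 and at 120 min; the 10 largest falls and 5 largest rises in each line; and per list and comparison up to 4 members past the threshold and up to 2 that were not. RIKEN and Gm models and unnamed probe sets were counted and passed over. These rules, the lists, the fits and the alternatives other than the added ones were fixed before the data were examined. Chosen after seeing the data were the 20 named genes among those called slower and not lower in KO at 0 min, any gene outside these rules, and the alternatives with background subtraction, with each set of experiments alone, without 3 arrays, with KO times rescaled and, for the lists, among genes not called lower in KO at 0 min and with an estimated correlation on top of these.

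The experiments left a common mark on the arrays of both lines. Deviations from the group means of same-numbered WT and KO arrays correlated at 0.38, 0.34, 0.12, 0.33 and 0.60 for experiments 1 to 5, against -0.076, -0.078, -0.007, -0.10 and -0.18 on average for arrays with other numbers. The labels tie the replicate number to the day. In experiments 3 and 4, though, the WT arrays correlated more highly with KO arrays of another number, so the correlations do not bear out the pairing in each experiment. The first component of these deviations held 33.9% of their variance. It lay above 0 in 24 of the 30 arrays of experiments 1 to 3 and in 0 of the 18 arrays of experiments 4 to 5, so these sets were treated as batches, each of which holds both lines. The fit reported here had no replicate block, as fixed beforehand, and the blocked fit was run as an alternative.

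Alternatives were quantile normalization, centring on ribosomal protein genes or on the median, no filter or a filter at the 75th percentile, the replicate block, a block by experiment and line, empirical Bayes without trend and robust, array weights, each replicate left out, a slope over 30 to 120 min, the difference of the 120 min changes, a slope per experiment and line, and, as added, subtraction of each array's 5th percentile with a floor of 16 on the linear scale, experiments 1 to 3 and 4 to 5 alone, KO times multiplied by 0.908 (the median ratio of KO to WT slope of 145 genes with a mean slope below -0.5 log2 per h), list tests among genes not called lower in KO at 0 min, and all but the 3 arrays with the lowest 95th percentile (replicate 1 of WT at 120 min, replicate 3 of WT at 0 min and replicate 3 of WT at 30 min). The fits were tested on simulated data with 27500 probe sets. The simulated noise was normal and independent between arrays, with no mark shared within an experiment and no floor. The shares recovered and the false calls therefore hold for such data and are not error rates of the measured arrays. A slope difference of 0.2 log2 per h was recovered for 90% of the changed probe sets in each direction and one of 0.4 for 98% (slower) and 100% (faster), with 1 false call. A difference of 0.5 log2 was recovered for 94% at 0 min, 97% at 120 min, 98% for the change in WT and 95% for the change in KO, with 7, 9, 8 and 2 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The slope difference expected from compression alone was computed per probe set from the WT group means less a background, scaled to the KO level at 0 min, with the background at the lowest of the 10 group means or at the arrays' median 5th percentile. A search for AU-rich motifs in 3' untranslated regions was not made, since no such sequences were at hand.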

Results

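Log2 signals of 27500 probe sets were compared between mouse embryonic fibroblast lines with Zfp36 (WT) and with Zfp36 disrupted (KO). Both genotypes were given serum for 90 min and then actinomycin D, which stops transcription, for 0, 30, 60, 90 or 120 min. Zfp36 encodes tristetraprolin (TTP), a protein that binds AU-rich elements in messenger RNA and promotes its deadenylation and decay. Each group held n = 5 arrays from 5 experiments, apart from KO at 0 min and KO at 60 min with n = 4. Array medians lay between 8.47 and 8.56, and signals near 8 were at the floor of the measurement. From the labels each genotype appears to be 1 cell line, which they do not state outright, and if so a difference between the lines is not tied to Zfp36 by the comparison itself. The log base was inferred and the authors' background correction is not given in the sources used here, so that folds and halving times are those of the deposited signal.

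Zfp36 itself was measured by 1 probe set among those tested. Where it lies relative to the disrupted part of the gene is not given in the sources used here, so its signal does not check the genotype. At 0 min the 5 WT arrays gave log2 signals of 9.84, 10.14, 9.83, 9.69 and 9.83, and the 4 KO arrays gave 9.60, 9.58, 9.28 and 9.59, each KO array below each WT array. The KO mean was 9.51 ± 0.16 (SD, n = 4) against 9.86 ± 0.16 in WT (SD, n = 5), a difference of -0.35 ± 0.090 (SE; limma adjusted p = 0.00245). It was -0.45 in experiments 1 to 3 (adjusted p = 0.00251) and -0.17 in experiments 4 and 5, which hold 1 KO array at 0 min. It was not past the threshold without replicate 3 (-0.28, adjusted p = 0.0551). At 30 min the arrays lay between 8.46 and 9.26 in WT and between 8.47 and 8.86 in KO. By 120 min the signal was 8.17 ± 0.080 in WT, a 3.23-fold fall to near the floor, and 8.12 ± 0.039 in KO, at the floor after a fall of at least 2.60-fold. The slopes of Zfp36 differed by 0.17 log2 per h (adjusted p = 0.746). The relatives measured were Zfp36l1, which was 0.37 log2 higher in KO at 0 min (adjusted p = 0.000922), and Zfp36l2, with a difference of 0.022 at 0 min (adjusted p = 0.94).

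The comparison of slopes asks which transcripts fell more slowly after actinomycin D in the line without TTP. Ier3, an immediate-early gene that acts in cell survival and which the study followed up on these samples, had the highest slope difference among the genes called slower in KO. The lines did not differ past the threshold at 0 min, with log2 signals of 12.30 ± 0.059 in WT (SD, n = 5) and 12.35 ± 0.046 in KO (SD, n = 4; limma adjusted p = 0.848), where the array maxima lay between 13.28 and 13.43. At 120 min WT had reached 9.94 ± 0.23 and KO 11.59 ± 0.10, a 3.14-fold higher signal in KO (adjusted p = 5.23e-16). Its slope was -1.27 log2 per h in WT and -0.38 in KO, which are signal halving times of 47.4 and 156.4 min. Both lines began near the top of the range, at 12.30 and 12.35, where saturation of the array cannot be told apart. The difference of 0.88 ± 0.092 (SE; adjusted p = 2.75e-09) had the same sign in 5 of 5 experiments. It was 0.84 in experiments 1 to 3 (adjusted p = 1.55e-09) and 0.94 in experiments 4 and 5 (adjusted p = 0.0475).

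**Figure D1:**
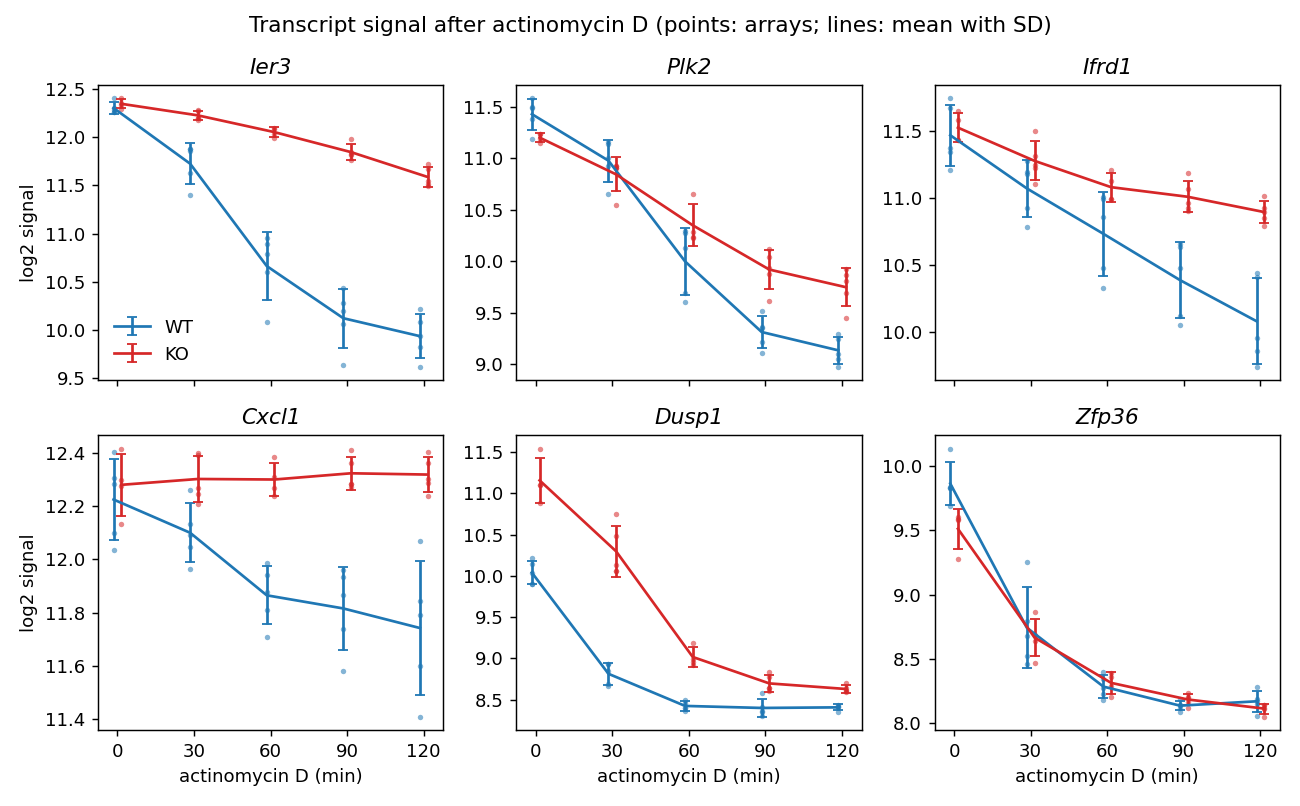
Log2 signal of Ier3, Plk2, Ifrd1, Cxcl1, Dusp1 and Zfp36 (vertical axis) against minutes of actinomycin D (horizontal axis) in WT and KO, with points for arrays and lines for group means with SD. The Ier3 means part from 12.30 and 12.35 at 0 min to 9.94 in WT and 11.59 in KO at 120 min.

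Among the 16 genes with the highest slope differences, 6 were not lower in KO at 0 min: Ier3, Mllt11, Plk2, Ifrd1, Smad1 and Clcf1. Plk2, a polo-like kinase induced by serum and by p53, halved in 48 min in WT and 78.5 min in KO (slope difference 0.49 ± 0.090, adjusted p = 0.000966) and was 1.53-fold higher in KO at 120 min. At 0 min its difference of -0.23 did not pass (adjusted p = 0.184, or 0.0447 with the replicate block). Smad1, which transmits signals of bone morphogenetic proteins, halved in 72.5 and 136.9 min (difference 0.39 ± 0.075, adjusted p = 0.00154) and was 2.02-fold higher in KO at 120 min. Its difference of 0.23 at 0 min had an adjusted p of 0.0651, or 0.0162 with the replicate block and 0.0221 without replicate 2. Ifrd1 halved in 86.8 min in WT and 199.9 min in KO (difference 0.39 ± 0.080, adjusted p = 0.003). Clcf1, a cytokine of the interleukin 6 family, had slopes of -0.33 in WT and 0.040 in KO (difference 0.37 ± 0.081, adjusted p = 0.00697), and Mllt11, which was already 0.79 log2 higher in KO at 0 min, had -0.39 and 0.13 (difference 0.52 ± 0.044, adjusted p = 5.19e-12).

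The other 10 of the 16 were lower in KO at 0 min and so began nearer to the floor. Irx3, a homeobox transcription factor, had a slope of -0.94 in WT and -0.097 in KO (difference 0.84 ± 0.056, adjusted p = 1.41e-15), but its KO mean was 8.41 at 0 min, with a KO minus WT difference of -2.00. Slope differences were 0.60 for the kinase gene Nuak2, 0.53 for Arc, 0.53 for the MAP kinase phosphatase Dusp4 and 0.51 for the cytokine signalling inhibitor Cish. They were 0.37 for Ppp1r12b, 0.36 each for Rab9, Cnksr3 and Myl6, and 0.35 for the nuclear noncoding RNA Neat1 (adjusted p = 0.0209). The KO signal of Nuak2 was at the floor at 60 and 120 min.

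Among the 8 genes named as faster in KO, 7 were higher in KO at 0 min. Dusp1, the phosphatase that turns off p38 MAP kinase, was 2.17-fold higher in KO at 0 min and fell from 11.16 to 8.63 there and from 10.04 to 8.41 in WT (slope difference -0.57 ± 0.15, adjusted p = 0.0393). Its fall over the first 30 min was larger in WT, to 8.81 against 10.30 in KO, and from 60 min the WT signal stayed between 8.40 and 8.43, near the floor. Dact1 (-0.56 ± 0.051, adjusted p = 8.29e-11), Chac1 (-0.44), Foxq1 (-0.32), the repressor Hic1 (-0.27), Cdk5r1 (-0.26) and the transcription factor Klf2 (-0.25) were likewise higher in KO at 0 min, and Chac1 was at the floor in both lines at 120 min. The WT means of Foxq1 (8.35 to 8.39) and Hic1 (8.27 to 8.41) were near the floor at all 5 times, and their WT slopes were not past the threshold (adjusted p = 0.919 and 0.128), so that there was no WT fall to compare. After subtraction of background, the slope differences of Dusp1 (adjusted p = 0.785), Dact1 (0.992), Chac1 (0.711), Klf2 (0.607) and Cdk5r1 (0.109) were not past the threshold, and neither was that of Arc among those named as slower (0.427). Sox9, which drives cartilage formation, had a slope difference of -0.28 ± 0.075 (adjusted p = 0.0485) with a difference of 0.16 at 0 min (adjusted p = 0.408).

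In all, 199 probe sets of 156 named genes fell slower in KO and 63 of 50 genes faster, which became 365 and 96 with the replicate block. After background subtraction there were 165 and 19. With KO times multiplied by 0.908, the median ratio of KO to WT slope of 145 fast-falling genes, there were 121 slower and 84 faster. Of the slower ones, 72 of 53 genes were not lower in KO at 0 min (155 with the block, 40 with KO times so rescaled). Of the faster ones, 2, Sox9 and Frmd6, were not higher in KO at 0 min, though Frmd6 was so with the replicate block (adjusted p = 0.0336) and without replicate 4 (0.00238), and Sox9 without replicate 3 (0.0268). Picked after these values were seen, the 72 also held the apoptosis inhibitor Mcl1 (slope difference 0.30 ± 0.066, adjusted p = 0.00734), with halving times of 63.6 and 93.4 min. Others among them were Lonrf1 (0.35), Plk3 (0.33), the receptor gene Epha2 (0.28), Phlda1 (0.27, from 12.37 in KO at 0 min) and the Notch coactivator Maml1 (0.26). For 15 of the 16 genes named as slower, each slope of a KO experiment lay above each WT slope, and 7 of the 8 named as faster were apart the other way. These genes were chosen for their slopes, which favours such a parting. Over all 27500 probe sets, the KO slopes lay above in 522 (1.9%) and below in 223 (0.81%), where chance gives 0.4% each.

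The count of 199 was 104 in experiments 1 to 3 and 120 in experiments 4 and 5, with 34 called in both, and that of 63 was 47 and 52. Without replicate 1, 2 or 4 the count of 199 became 80, 106 or 102 and that of 72 became 35, 42 or 32, and without replicate 2 that of 63 became 40. Without the arrays at 0 min, 63 fell slower and 31 faster. Of the slower ones 16 were not called lower in KO at 0 min, and of the faster ones 0 were not called higher there.

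Some calls of named genes ended when 1 replicate was left out (adjusted p in brackets). Without replicate 1 these were Ifrd1 (0.145), Clcf1 (0.156), Neat1 (0.0862), Mcl1 (0.125), Phlda1 (0.158), Plk3 (0.13), Socs5 (0.0632), Cebpd (0.226), Trp53inp1 (0.247), Dusp1 (0.13), Sox9 (0.143) and Frmd6 (0.193). Without replicate 2 they were Clcf1 (0.0681), Cebpd (0.211), Trp53inp1 (0.547), Rgs16 (0.22), Dusp1 (0.13), Klf2 (0.062), Bmp2 (0.19), Sox9 (0.61) and Frmd6 (0.482). Without replicate 3 they were Neat1 (0.114), Cebpd (0.0853), Dusp1 (0.111), Klf2 (0.0763), Bmp2 (0.179), Spry4 (0.175) and Frmd6 (0.0942). Without replicate 4 they were Neat1 (0.103), Mcl1 (0.0527), Epha2 (0.0634), Phlda1 (0.211), Cebpd (0.17), Trp53inp1 (0.21), Rgs16 (0.101), Dusp1 (0.204), Klf2 (0.192), Spry4 (0.139) and Sox9 (0.105). Without replicate 5 they were Phlda1 (0.108), Trp53inp1 (0.0995), Rgs16 (0.0711), Dusp1 (0.0656), Klf2 (0.0995), Bmp2 (0.302), Spry4 (0.0608), Sox9 (0.13) and Frmd6 (0.0996). After background subtraction those of Trp53inp1 (0.0546), Frmd6 (0.0582), Bmp2 (0.256) and Spry4 (0.144) ended too. With KO times rescaled, those of Neat1 (0.0609), Mcl1 (0.113), Phlda1 (0.338), Cebpd (0.228) and Trp53inp1 (0.153) ended.

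**Figure D2:**
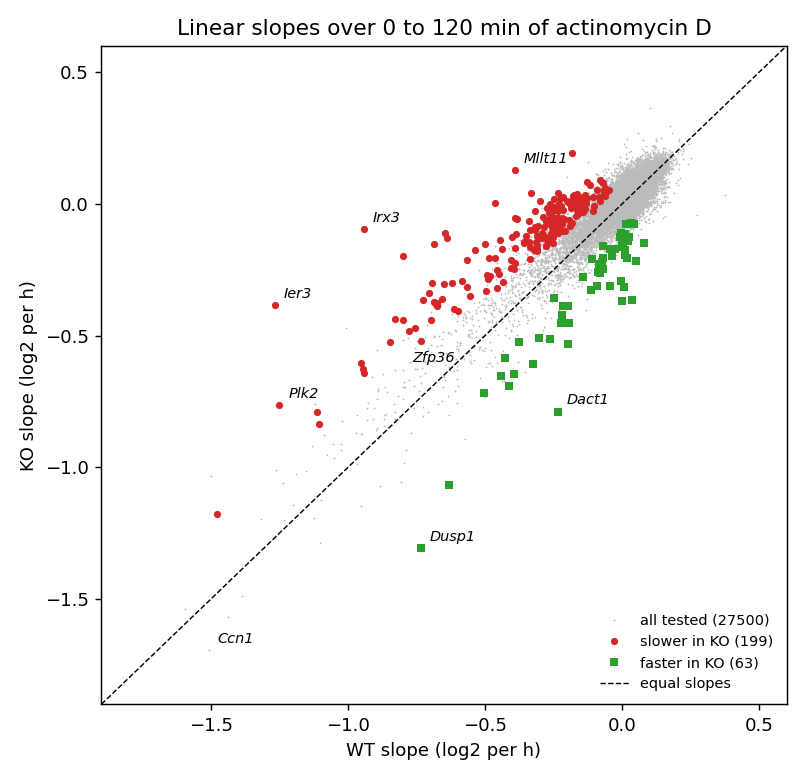
Slope of log2 signal on time in WT (horizontal axis, log2 per h) and KO (vertical axis, log2 per h) for the 27500 probe sets, with the 199 that fell slower in KO in red, the 63 that fell faster in green and equal slopes as a dashed line. 1 probe set lies outside the axes.

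The list of p53 targets and growth arrest genes, which also holds Cdkn2a and Cdkn1b, is called p53 targets for short in places. Of its 18 measured members, 5 fell slower in KO (10 with a slope difference above 0 adjusted over the list alone), 0 faster and 13 did not pass. The 5 were Plk2 (0.49), Plk3 (0.33), Phlda1 (0.27), Mdm2, which degrades p53 (0.17 ± 0.029, adjusted p = 0.000208), and Trp53inp1 (0.21, adjusted p = 0.0326, or 0.547 without replicate 2). The list shifted towards slower fall (limma camera adjusted p = 4.21e-09, and adjusted p = 0.00153 with an estimated correlation), and it did so without each replicate. At 0 min 8 of the 18 were lower in KO, Mdm2 and Trp53inp1 among them, and the list was shifted down (adjusted p = 0.0366), which was lost with an estimated correlation (adjusted p = 0.991). The slope shift was past the threshold after background subtraction (adjusted p = 1.35e-10, or 0.000374 with an estimated correlation), among genes not lower in KO at 0 min (10 of the 18; 0.000105, or 0.014) and with KO times rescaled (3.05e-06, or 0.016).

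Of 16 measured reported TTP targets, 1, the neutrophil chemokine Cxcl1, fell slower in KO (1 adjusted over the list alone) and 15 did not pass. With the replicate block there were 2, with Pim1 (0.21, adjusted p = 0.0263) the other one. The slope of Cxcl1 was -0.25 in WT and 0.019 in KO (difference 0.27 ± 0.050, adjusted p = 0.000967), and its signal, 12.28 in KO at 0 min and so near the top of the range, was 1.49-fold higher in KO at 120 min. The slope difference of Cxcl1 was 0.23 in experiments 1 to 3 (adjusted p = 0.000984) and 0.31 in experiments 4 and 5 (adjusted p = 0.418). This list shifted up with a median of 0.069 (adjusted p = 0.00257), which was not so with an estimated correlation (adjusted p = 0.242) or without replicate 3 (adjusted p = 0.106). It was so after background subtraction (0.00189), among genes not lower at 0 min (0.000327) and with KO times rescaled (0.0152), though none of the 3 with an estimated correlation (adjusted p = 0.143, 0.108 and 0.387). By fry, which asks whether the members of a list move on balance in 1 direction and does not compare them with other genes, the slope differences of these targets were above 0 (adjusted p = 0.0349).

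The list of cytokines, chemokines and growth factors shares Cxcl1 and other genes with the reported TTP targets, so their shifts are not separate results. It had 1 of 28 slower (Cxcl1), 1 faster (Bmp2, -0.11) and 26 not past the threshold, with 2 and 1 adjusted over the list alone and 2 slower with the replicate block (Bmp4, 0.28, adjusted p = 0.0271). The upward shift of the cytokine list (adjusted p = 0.0314) was lost with an estimated correlation (adjusted p = 0.299), without replicate 1 (0.0741), without replicate 3 (0.212), after background subtraction (0.0675), among genes not lower at 0 min (0.348) and with KO times rescaled (0.0964), and fry's test of movement in 1 direction did not pass (0.1). MAP kinase and receptor feedback genes had 3 of 20 slower (Dusp4, Socs5 and Rgs16), 3 faster (Dusp1, Rgs2 and Spry4) and 14 not past the threshold, with 6 and 3 adjusted over the list alone. That list also shifted up (adjusted p = 0.0314), but not with an estimated correlation (adjusted p = 0.299) or without replicate 1 (0.0772), replicate 3 (0.106) or replicate 5 (0.0659), nor with all probe sets of each gene (0.131), after background subtraction (0.0675) or with KO times rescaled (0.722), and fry's test did not pass (0.058). Among genes not lower in KO at 0 min the test had the opposite sign (adjusted p = 0.896). The 5 cartilage and bone markers shifted down (adjusted p = 0.0194; adjusted p = 0.277 with an estimated correlation, 0.0772 without replicate 1 and 0.124 without replicate 2; 0.0596 in fry's own test), with Sox9 the single member called.

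In the other lists, immediate-early transcription factors had 1 of 33 slower (Cebpd, 0.29 ± 0.078) and 1 faster (Klf2), with 3 and 2 adjusted over the list alone, 2 (with Mafk) and 3 (with Id2 and Atf3) with the replicate block and a list adjusted p of 0.495, or 0.0415 after background subtraction (adjusted p = 0.721 with an estimated correlation). NF-kappaB feedback genes had 0 of 16 called (4 and 1 adjusted over the list alone, and 2 slower with the replicate block, Birc2 and Birc3; adjusted p = 0.145). The TTP family had 0 of 3 called. Its shift relative to other genes was not past the threshold (camera adjusted p = 0.245), while its slope differences moved on balance upward against no change (fry adjusted p = 0.0224). The serum response and matricellular genes (0.747), mRNA decay factors (0.943), ribosomal proteins (0.655), glycolysis (0.992), fibroblast matrix and stroma (0.747), interferon-stimulated (0.892) and cell cycle genes (0.892) had 0 members called and did not pass by camera or fry. The same held for the epithelial (adjusted p = 0.783), muscle (0.85), endothelial (0.253), macrophage and blood (0.386) and neural markers (0.655) and the sex-linked genes (0.655). Adjusted over the list alone, 1 muscle marker had a slope difference below 0, while 0 of the 8 fell over 120 min in KO. Median, mean and test differed in sign for the mRNA decay factors, interferon-stimulated genes and muscle markers.

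The change over 120 min in WT shows which transcripts were short-lived with TTP present. The largest fall was that of the ERK phosphatase Dusp5, from 11.75 to 8.70 (8.33-fold, -3.06 ± 0.10 log2, adjusted p = 1.34e-26, n = 5 and 5), and Ier5 fell 7.4-fold, the matricellular gene Ccn1 7.1-fold, Cited2 6.62-fold and the nuclear receptor Nr4a1 6.51-fold. Of 33 immediate-early transcription factors, 30 fell, among them Junb (-2.53), Cebpb (-2.49), Myc (-2.22) and Fos (-1.38), 0 rose and 3 did not pass. MAP kinase feedback genes fell in 17 of 20 (Dusp5; Dusp6, -2.41), NF-kappaB feedback genes in 12 of 16 (Nfkbia, -2.30; Tnfaip3, -1.81) and p53 targets in 15 of 18 (Gadd45g, -2.40; Btg1, -2.38). These lists shifted down, with adjusted p of 6.41e-41 for the transcription factors, 1.84e-27, 1.19e-11 and 2.75e-16.

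Of the reported TTP targets, 8 of 16 fell in WT, among them Socs3 (-2.22), Myc (-2.22), Pim1 (-1.08) and Cxcl1 (-0.48), and 8 did not pass, such as Ptgs2 (-0.084). The list shifted down (adjusted p = 6.23e-06). It shares Fos and Myc with the transcription factors, Socs3 with the MAP kinase feedback genes and Ptgs2 with the serum response genes. With the cytokines, chemokines and growth factors it shares several genes, among them Cxcl1, Cxcl2, Il6, Csf3 and Lif. Ier3, which is in none of the lists, fell 5.15-fold. All 3 measured TTP family genes fell (adjusted p = 2.74e-05). Among cytokines, chemokines and growth factors 9 of 28 fell, such as Bmp4 (-1.32) and Lif (-0.79), 2 rose, with Ccl5 (0.32) the higher, and 17 did not pass, Il6 (0.056) among them. The downward shift (adjusted p = 0.0397) was lost with an estimated correlation (adjusted p = 0.368). In the serum response list 5 of 17 fell, among them Ccn2 (-0.94), with a list adjusted p of 0.151.

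Relative to the array average, 10 of 36 ribosomal protein genes rose, such as Rps6 (0.31) and Rpl14 (0.29), 1 fell (Rpl12, to 8.08 at the floor) and 25 did not pass. The upward shift (adjusted p = 0.0153) was lost with an estimated correlation (adjusted p = 0.47). Of 11 glycolysis genes 2 rose, with Tpi1 (0.33) the higher, and 9 did not pass (adjusted p = 0.092, or 0.034 with the replicate block, and adjusted p = 0.447 with the block and an estimated correlation). Of 34 mRNA decay factors 6 rose (Hnrnpd, 0.24) and 8 fell (Dcp1a, -0.58; Cnot2, -0.58). Of 18 interferon-stimulated genes 2 rose and 3 fell (Ifit2, -0.44), and 2 of 21 cell cycle genes fell, with Cdc20 (-0.43) the lower. Of 26 fibroblast matrix genes 1 rose and 2 fell (Pdgfra, -0.58; Pdgfrb, -0.35). Of the marker lists, 2 muscle markers and 1 epithelial marker rose, 1 cartilage marker fell (Sox9, -0.66) and 0 of the endothelial, macrophage and blood, neural and sex-linked genes were called. Adjusted over the list alone, 31 transcription factors and 1 cell cycle gene fell, and 11 ribosomal proteins, 1 serum response gene and 1 p53 target rose, while the other counts stayed as given. With the replicate block, counts moved by more than 1.5 times to 4 serum response genes, 1 p53 target, 5 glycolysis and 3 fibroblast matrix genes higher and 4 cell cycle genes lower. Median, mean and test differed in sign for the mRNA decay factors, interferon-stimulated genes and cartilage markers. The largest rises in WT were small, led by Tmem120a (1.43-fold, 0.51 ± 0.073 log2, adjusted p = 2.94e-07), Card19 (0.49) and Dnajc15 (0.42).

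Over all probe sets, 2757 rose and 3853 fell in WT, and 246 of the falls were of 1 log2 or more. The counts were 1487 and 3194 in experiments 1 to 3 and 4024 and 4092 in experiments 4 and 5. With the replicate block 4217 rose, and 1633 rose without replicate 4. The split between rises and falls depended on scaling, with 5606 and 3406 after median centring, 4096 and 3753 after quantile normalization and 1443 and 4851 after centring on ribosomal protein genes.

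The change over 120 min in KO shows which transcripts were short-lived without TTP. Of the largest falls, that of Ccn1 was 8.97-fold (-3.17 ± 0.17 log2, adjusted p = 3.53e-19, n = 4 and 5), and Dusp5 fell 7.34-fold, Nr4a1 6.71-fold, Dusp1 5.76-fold, Myc 4.76-fold and Dusp2 4.57-fold. Immediate-early transcription factors fell in 29 of 33 (Junb, -2.25; Fos, -1.43), MAP kinase feedback genes in 17 of 20 (Dusp6, -2.24), NF-kappaB feedback genes in 10 of 16 (Nfkbia, -2.24; Tnfaip3, to 7.99 at the floor) and p53 targets in 11 of 18 (Gadd45g, -1.24; Btg2, -1.67), with 2 p53 targets higher. The list adjusted p were 1.06e-44, 1.53e-26, 1.58e-09 and 1.61e-09. Ier3 fell 1.69-fold.

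Of the reported TTP targets in KO, 5 of 16 fell, such as Socs3 (-2.03) and Pim1 (-0.65), 3 rose, with Csf3 (0.21) the highest, and 8 did not pass, among them Cxcl1 (0.039) and Lif (-0.33, adjusted p = 0.171). The downward shift (adjusted p = 0.0069) was lost with an estimated correlation (adjusted p = 0.191). The 3 TTP family genes fell (adjusted p = 0.000283), though Zfp36l1 (-0.30) was not past the threshold without replicate 2 (adjusted p = 0.0623) or replicate 3 (0.0618). Cytokines, chemokines and growth factors had 6 of 28 lower (Bmp4, -0.80) and 2 higher (adjusted p = 0.391), and serum response genes 6 of 17 lower (Ccn2, -1.28) and 2 higher (adjusted p = 0.186). Ribosomal protein genes had 10 of 36 higher (Rps6, 0.30) and 1 lower (Rpl12, -0.62), with a shift (adjusted p = 0.000944) lost with an estimated correlation (adjusted p = 0.348). Of 11 glycolysis genes, 2 rose, with Tpi1 (0.36; adjusted p = 0.102 without replicate 3) the higher (list adjusted p = 0.0665, or 0.0271 with the replicate block, and adjusted p = 0.487 with the block and an estimated correlation). Of 34 mRNA decay factors, 5 rose (Hnrnpd, 0.23) and 5 fell (Dcp1a, -0.62). Interferon-stimulated genes had 2 of 18 higher and 3 lower (Irf1, -0.42), cell cycle genes 2 of 21 lower (Plk1, -0.31), and fibroblast matrix genes 1 of 26 higher and 2 lower (Pdgfrb, -0.36). In the marker lists 1 epithelial (Krt7, 0.15) and 1 muscle marker rose, 1 cartilage marker fell (Sox9, -1.13), and 0 of the others were called. Adjusted over the list alone, falls numbered 6 for TTP targets, 31 for transcription factors, 7 for cytokines, 11 for NF-kappaB genes, 7 for serum response genes, 4 for interferon-stimulated genes, 2 for cartilage markers and 1 for fibroblast matrix genes. Rises so adjusted numbered 4 for cytokines, 4 for interferon-stimulated genes, 11 for ribosomal proteins, 3 for glycolysis genes and 0 for fibroblast matrix genes, and the other counts stayed as given. With the replicate block, counts of rises moved by more than 1.5 times to 1 transcription factor, 5 cytokines, 5 serum response, 6 glycolysis, 3 fibroblast matrix, 4 interferon-stimulated and 2 cell cycle genes, and those of falls to 1 glycolysis gene, 6 cell cycle genes and 2 cartilage markers. Median, mean and test differed in sign for the mRNA decay factors, cell cycle genes, endothelial markers and sex-linked genes. The largest rises were of Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (1.47-fold, 0.55 ± 0.17 log2, adjusted p = 0.0153), Nudt6 (0.50) and Sat1 (0.50). That of Tnfrsf11b was not past the threshold without replicate 1 (adjusted p = 0.0876) or replicate 3 (0.0925).

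Over all probe sets, 3268 rose and 2924 fell in KO, 183 by 1 log2 or more, and 2400 fell in both lines, where 410 would be shared if the lines were independent. The counts were 2847 and 2444 in experiments 1 to 3. Those of experiments 4 and 5 are left out, since KO at 0 min has 1 array there. Without replicate 2, 1767 rose, and without replicate 3, 2162. Centring on ribosomal protein genes gave 1381 and 5172, and median centring gave 4649 and 2605. Tested against each other, the changes over 120 min were higher in KO for 152 probe sets and lower for 43 (401 and 127 with the replicate block).

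The comparison at 0 min shows how the serum-treated lines differed before actinomycin D. The tubulin gene Tubb2b was 4.49-fold higher in KO (2.17 ± 0.14 log2, n = 5 and 4) and Cdkn2a, which encodes the growth-arrest proteins p16 and p19, 4.14-fold (8.44 and 10.49; adjusted p = 2.05e-15). The imprinted zinc finger gene Plagl1 and Ramp3 were at the floor in WT (7.86 and 8.01), so that they were at least 3.92-fold and 3.39-fold higher, as computed against the highest 5th percentile of an array (8.13). Ldhb (3.84-fold), Cdsn (3.51-fold), Cyba (3.5-fold) and Bhlhb9 (3.36-fold) were also among the highest. Among the lowest in KO, the fibulin gene Efemp1 differed by -3.25 ± 0.068 log2 (9.49-fold), the cadherin Cdh11 by -3.13 ± 0.050 (8.77-fold), Tgfbi by -2.68 ± 0.35 (6.41-fold) and the gelatinase Mmp2 by -2.58 (5.97-fold), followed by Slc4a4, Hivep3, Emb and Ptgis. Cdkn2a was 2.21 log2 higher in experiments 1 to 3 and 1.59 higher in experiments 4 and 5, which hold 1 KO array at 0 min.

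Cell cycle genes were higher in KO in 9 of 21 (18 of 21 with the replicate block) and lower in 0, among them Mcm7 (0.82) and Mcm2 (0.63). The list shifted up (adjusted p = 0.0366, or 3.64e-06 with the block), which was lost with an estimated correlation (adjusted p = 0.991, or 0.903 with the block). Of 18 p53 targets and growth arrest genes, 8 were lower in KO, among them the arrest genes Cdkn1a (2.33-fold), Ccng1 (2.27-fold) and Gadd45g (-1.37), 3 were higher (Cdkn2a; Btg1, 0.45; Cdkn1b, 0.39) and 7 did not pass. The downward shift (adjusted p = 0.0366) was lost with an estimated correlation (adjusted p = 0.991). Immediate-early transcription factors went both ways, with 9 of 33 higher (Nr4a2, 1.30; Id2, 1.25; Klf4, 0.86) and 7 lower, as did MAP kinase feedback genes with 5 of 20 higher (Dusp1, 1.12) and 7 lower (Dusp4, -1.11). Fibroblast matrix genes had 6 of 26 higher (Pdgfra, 1.18) and 10 lower (Postn, -1.97; Fbln1, -1.12), and serum response genes 5 of 17 higher (Tnc, 1.68; Tagln, 1.15) and 5 lower (Actg2, -0.75).

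Among cytokines, chemokines and growth factors at 0 min, 7 of 28 were higher in KO (Il11, 2.72-fold; Lif, 0.81) and 9 lower (Inhba, -1.01). Il6 was lower in KO (-1.002 ± 0.36, adjusted p = 0.0363), and its difference was -1.49 in experiments 1 to 3 (adjusted p = 2.54e-09). In experiments 4 and 5, with 1 KO array at 0 min, the Il6 difference was 0.46, of the opposite sign. Its pooled call was lost without replicate 1 (adjusted p = 0.211), replicate 2 (0.182) or replicate 3 (0.166). Reported TTP targets had 4 of 16 higher (Ptgs2, 0.38; Csf3, 0.29) and 1 lower, and the TTP family 1 higher and 1 lower. NF-kappaB genes had 3 of 16 higher (Vcam1, 0.91) and 4 lower (Tnfaip3, -0.84; Birc3, -0.47), and mRNA decay factors 11 of 34 higher (Edc4, 0.43; Cnot6l, 0.40) and 4 lower (Zc3h12a, -0.34). Ribosomal proteins had 3 of 36 higher (Rpl22, 0.30) and 6 lower (Rpl12, -0.41), glycolysis genes 1 of 11 higher (Pgk1, 0.34) and 1 lower (Pfkp, -0.37), and interferon-stimulated genes 4 of 18 higher (Ifih1, 0.72; Bst2, 0.54) and 2 lower (B2m, -0.58). Of the marker lists, the epithelial and neural ones had 1 member higher each, with Tubb3 (0.86) in the latter, the endothelial one 1 lower (Eng, -0.99) and the muscle, macrophage and blood, and cartilage ones 0 called. Xist, which is transcribed from the inactive X chromosome of female cells, was lower in KO (8.84 against 9.93, -1.09 ± 0.26, adjusted p = 0.00144), while the Y-linked Eif2s3y and Uty differed by -0.010 and -0.014. Apart from the cell cycle and p53 lists, no list shifted at 0 min by limma's camera.

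Adjusted over the list alone, the genes higher and lower at 0 min were 9 and 8 transcription factors, 7 and 10 cytokines, 5 and 10 MAP kinase feedback genes, 5 and 6 NF-kappaB genes and 5 and 6 serum response genes. They were 4 and 8 p53 targets, 7 and 11 fibroblast matrix genes and 2 and 1 neural markers, and the other lists kept their counts. With the replicate block, counts moved by more than 1.5 times to 4 glycolysis genes, 1 muscle and 2 neural markers higher, and to 3 TTP targets, 2 glycolysis genes and 1 neural marker lower. Median, mean and test differed in sign for the TTP family, TTP targets, serum response genes, ribosomal proteins and muscle, endothelial and neural markers.

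Over all probe sets at 0 min, 3690 of 2439 genes were higher in KO and 3274 of 2065 genes lower, of which 95 and 152 differed by 1 log2 or more. The counts were 3389 and 3061 in experiments 1 to 3. Those of experiments 4 and 5 are left out, since KO at 0 min has 1 array there. Differences also ran along chromosomes. Among 2091 genes with a mean log2 signal above 10, the median KO minus WT difference was 0.033. It was 0.20 on chromosome 8 (115 genes, 62 of them higher and 9 lower in KO), 0.18 on chromosome 3 (121 genes), 0.14 on chromosome 5 (148 genes), -0.14 on chromosome 1 (120 genes) and -0.14 on chromosome 9 (111 genes). Each of these 5, the autosomes that passed and had a median beyond 0.1, gave a permutation p of 1e-04 against 10000 random gene sets, the smallest they can give (Bonferroni 0.0019). Chromosomes 2 (-0.093) and 15 (-0.079) gave the same p and Bonferroni value but lay within 0.1, though at -0.13 and -0.11 less the median of all, and chromosome 10 (-0.051) had a Bonferroni value of 0.0342. At 120 min these medians were 0.21, 0.21, 0.17, -0.071 and -0.067, where all these genes had a median of 0.068. Less the median of all, chromosomes 1 and 9 were at -0.17 and -0.18 at 0 min and at -0.14 and -0.14 at 120 min, and chromosome 2 went from -0.13 to -0.056.

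**Figure D3:**
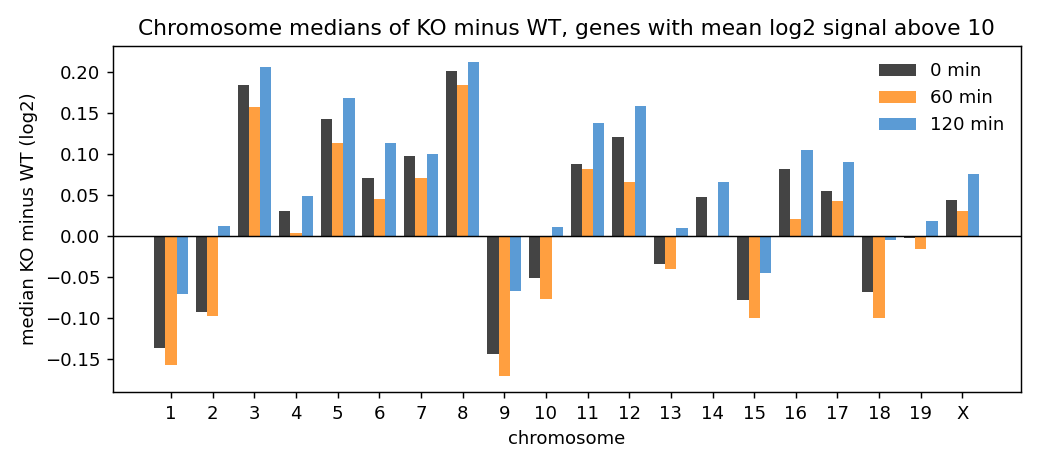
Median KO minus WT difference in log2 signal (vertical axis) of genes with a mean log2 signal above 10 on each chromosome (horizontal axis), with bars for 0, 60 and 120 min. Chromosome 8 is the highest at 0 min (0.20) and chromosome 9 the lowest (-0.14), and at 120 min they are at 0.21 and -0.067.

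The comparison at 120 min shows how the lines differed at the end of the chase. Genes that led at 0 min led again, with Tubb2b 4.53-fold higher in KO, Cdkn2a 4.26-fold and Cyba 4.15-fold, Ramp3 and Plagl1, at the floor in WT, at least 4.68-fold and 4.07-fold higher, and with Efemp1 (-3.18), Cdh11 (-2.83), Tgfbi (-2.77) and Mmp2 (-2.56) lowest. Among the highest 8 was also Mllt11, which had fallen slower in KO (3.44-fold). Bhlhb9 and Msln completed the highest 8, and Emb, Slc4a4, Ptgis and Nid2 the lowest.

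Of the reported TTP targets at 120 min, 5 of 16 were higher in KO, among them Lif (2.42-fold), Cxcl1 (0.58) and Ptgs2 (0.46), 1 was lower and 10 did not pass, such as Il6 (-0.52, adjusted p = 0.247). Cytokines, chemokines and growth factors had 8 of 28 higher (Il11, 1.54; Cxcl2, 0.43) and 8 lower (Csf1, -0.68; Inhba, -0.81, with adjusted p = 0.0643 without replicate 3). Of 18 p53 targets 7 were higher (Plk3, 0.91; Btg1, 0.80) and 5 lower (Ccng1, -1.11), and of 33 immediate-early transcription factors 9 were higher (Klf4, 2.49-fold; Nr4a3, 1.07) and 5 lower. Cell cycle genes were higher in 12 of 21 (Mcm4, 0.89; Mcm2, 0.74) and lower in 0, a shift (adjusted p = 0.0353, or 3.12e-05 with the replicate block) lost with an estimated correlation (adjusted p = 0.945, or 0.917 with the block). It was the single list past the threshold at 120 min.

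MAP kinase feedback genes at 120 min had 3 of 20 higher (Rgs2, 0.24) and 1 lower (Spred1, -0.39), and NF-kappaB genes 5 of 16 higher (Vcam1, 0.91; Bcl3, 0.28) and 3 lower. Serum response genes had 5 of 17 higher (Tnc, 1.60) and 7 lower (Ccn2, -0.68), and fibroblast matrix genes 7 of 26 higher (Pdgfra, 1.46) and 11 lower (Postn, -1.72). Higher and lower were 11 and 1 of 34 mRNA decay factors (Cnot7, 0.46), 4 and 3 of 36 ribosomal proteins (Rpl22, 0.30), 2 and 1 of 11 glycolysis genes (Pgk1, 0.32) and 5 and 2 of 18 interferon-stimulated genes (Bst2, 0.59). The TTP family had 2 higher (Zfp36l1, 0.50; Zfp36l2, 0.39, with adjusted p = 0.201 without replicate 1) and 0 lower. Of the markers, the epithelial list had 1 higher (Krt7, 0.23) and 1 lower, the muscle list 1 and 1, and the endothelial list 1 lower (Eng, -1.11). The macrophage and blood list had 2 lower, the neural list 1 higher (Tubb3, 0.79), the cartilage list 2 lower and the sex-linked list 1 lower (Xist, -1.59).

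Adjusted over the list alone, the genes higher and lower at 120 min were 9 and 6 transcription factors, 8 and 10 cytokines, 1 and 1 MAP kinase feedback genes, 5 and 8 serum response genes, 8 and 6 p53 targets and 11 and 3 mRNA decay factors. They were 3 and 1 glycolysis genes, 8 and 11 fibroblast matrix genes, 1 and 3 epithelial, 1 and 1 endothelial, 1 and 1 neural and 0 and 3 cartilage markers, and the other lists kept their counts. With the replicate block, counts moved by more than 1.5 times to 5 MAP kinase feedback genes, 4 glycolysis genes and 1 endothelial marker higher, and to 2 MAP kinase feedback genes, 4 mRNA decay factors, 1 cell cycle gene, 3 epithelial markers and 1 neural marker lower. Median, mean and test differed in sign for the cytokines, MAP kinase feedback, serum response, glycolysis and interferon-stimulated genes and the neural markers.

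Over all probe sets at 120 min, 5156 of 3250 genes were higher in KO and 3691 of 2397 genes lower, of which 96 and 127 differed by 1 log2 or more. The counts were 5054 and 3284 in experiments 1 to 3 and 3649 and 2939 in experiments 4 and 5.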

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

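The tests with rescaled KO times, those on the parts of the slower group and on the faster group, that without the 0 min arrays, that of array saturation and all those on Cdkn2a were chosen only after the result was seen, as were the alternatives with background subtraction and with each set of experiments alone.

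Slopes that differed between the lines, by a test of the difference itself, were found for 199 probe sets slower in KO and 63 faster, and the changes over 120 min differed for 152 higher and 43 lower in KO. The named slope differences were 0.88 (Ier3), 0.84 (Irx3), 0.60 (Nuak2), 0.53 (Arc), 0.53 (Dusp4), 0.52 (Mllt11), 0.51 (Cish), 0.49 (Plk2), 0.39 (Ifrd1), 0.39 (Smad1), 0.37 (Clcf1), 0.37 (Ppp1r12b), 0.36 (Rab9), 0.36 (Cnksr3), 0.36 (Myl6) and 0.35 (Neat1) log2 per h. Those of genes faster in KO were -0.25 (Klf2), -0.26 (Cdk5r1), -0.27 (Hic1), -0.28 (Sox9), -0.32 (Foxq1), -0.44 (Chac1), -0.56 (Dact1) and -0.57 (Dusp1). Lists with shifted slopes had adjusted p of 0.00257 (reported TTP targets), 0.0314 (cytokines, chemokines and growth factors), 0.0314 (MAP kinase and receptor feedback), 4.21e-09 (p53 targets and growth arrest) and 0.0194 (cartilage and bone markers), and with an estimated correlation the p53 list alone kept its call (adjusted p = 0.00153).

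Random regrouping was tested with 100 of the 126 possible splits for each comparison. Of those drawn, 13 to 15 parted as many replicate pairs as the real split, the real one included. So few splits do not exclude chance as the source of these counts. Among them the highest other gave 0 probe sets for the slopes, 5317 at 0 min, 3253 at 120 min and 3825 for the change in KO, each under the real split. For the slopes the real split gave 262 probe sets and the highest other 1, with 1 split as large, the real one. The other splits mix the lines, and the slope fit has 1 intercept per side, so level differences between the lines enter its spread there. This lowers the counts of the other splits, which therefore do not show how many probe sets chance would give. At 0 min the real split gave 6964 and the highest other 6008, a split that put 4 of the 5 WT arrays on 1 side and replicate 3 of WT with the KO arrays. At 120 min the values were 8847 and 4555 and for the change in KO 6192 and 4272, again with 1 split as large. For the change in WT 2 splits were as large, the real one with 6610 and another with 6893 that kept 4 of the 5 arrays at 0 min together with replicate 4 at 120 min, and the splits that parted as many pairs as the real one reached 1838.

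The excess of slower over faster probe sets in KO may reflect the absence of TTP, and the sets of experiments are argued against as its source (of probe sets called slower in 1 set, 95.8% or more had the same sign in the other), but technical explanations remain open for much of it. The 199 began lower in KO (median -0.27, 76.9% below 0), but their slopes share the 0 min arrays and simulated unchanged arrays gave -0.096 and 98.5%, whereas 63 called without the 0 min arrays had a median of -0.42 (-0.53 to -0.22), as compression near the floor needs. The 43 called slower and not lower at 0 min in experiments 4 and 5 alone had a median of 0.11 (0.056 to 0.18) at 0 min in experiments 1 to 3. This does not decide on compression. They were picked for their level, from 1 KO and 2 WT arrays at 0 min of the same lines, which favours that outcome. The intervals here are bootstraps over probe sets or genes and not over arrays. For the 72 not lower over all experiments compression cannot be told apart, because their choice by level fixes the sign of its prediction (-10.1% of the slope difference, -17.2 to -1.6). Saturation is argued against for the 72 as a group, with a median KO signal of 9.77 at 0 min (9.72 for the 67 at 12 or below, a group set by that level). It cannot be told apart for the 5 above 12 at 0 min (Ier3, Phlda1, Hmgcs1 and 2 of Cxcl1), picked for that level. For the other 127 compression cannot be told apart either. It predicts 98.1% (95.5 to 100.3) with the background at the lowest group mean and 45.9% (40.4 to 51.2) with the arrays' 5th percentile. After subtraction of the latter all 127 differences stayed above 0 (median 0.18 before and 0.38 after), while the median SE went from 0.038 to 0.095 and 61 calls ended. The differences of the 72 also all stayed above 0 (median 0.19 before and 0.36 after), and 10 of their calls ended. The medians of both groups moved alike, but 86.1% of the calls of the 72 stayed against 52% of those of the 127. The median SE of the 72 went from 0.043 to 0.078. Since the 72 were picked for a KO level not called lower at 0 min, this difference does not decide on compression. Nor can compression be told apart for the 63 faster ones, from WT nearer the floor. There it predicts 70.6% (16.5 to 120.0), and subtraction ended 44 calls as the median went from -0.17 to -0.32 and the median SE from 0.037 to 0.10. A weaker action of actinomycin D in the KO line cannot be told apart, because 145 fast-falling genes had a median slope difference of 0.075 (0.053 to 0.11), and with KO times rescaled by 0.908 the slower calls kept were 55.6% (40 of 72; median difference 0.19 before and 0.18 after) and 63.8% (81 of 127; 0.18 and 0.17), with Ier3 at 0.84 (adjusted p = 4.12e-08).

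The many differences between the lines at 0 min may in part reflect chromosomes gained or lost in 1 of the lines. In a test fixed before the result was seen, 5 autosomes (1, 3, 5, 8 and 9) passed the permutation test with medians of bright genes beyond 0.1, as that explanation needs (chromosomes 2 and 15, at -0.093 and -0.079, had the same p but lay within 0.1), though at 120 min chromosomes 1 and 9 were at -0.071 and -0.067 (-0.14 and -0.14 less the median of all bright genes). The 5 autosomes held 300 of the 855 bright genes called at 0 min, so most of the called genes lie elsewhere. Of all 2091 bright genes they held 120, 121, 148, 115 and 111. Among the 300, 260 went in the direction of their chromosome. These autosomes were picked for the median of the same differences, which favours that outcome, so it decides nothing. A strain segment kept around Zfp36 is argued against as the source, with an odds ratio of 0.85 (0.61 to 1.18) for 200 genes beside Zfp36 to be past the threshold. Absence of TTP before actinomycin D, and any other difference between single lines, stay open as untested.

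Cdkn2a, at 8.44 in WT and 10.49 in KO at 0 min, may have been lost in WT with a short segment, or raised in a KO line with less p53 activity, the usual states of fibroblast lines in long culture. From Cdkn2a to Tusc1, 4 of 5 neighbouring measured genes were at least 0.5 log2 higher in KO (with Cdkn2b, Elavl2 and Tusc1 at 8.36, 8.58 and 8.29 in WT), but this run was picked for these values, which therefore decide nothing, so a short loss cannot be told apart. The 20 neighbouring genes had a median difference of 0.010 (-0.034 to 0.073), but many were near the floor in both lines, where a loss cannot show. The brighter neighbours argue against loss of a longer segment in WT. Mtap beside Cdkn2a was higher in WT (11.88) than in KO (10.96). Mllt3, Klhl9, Plaa and Ift74 were at 10.16, 10.37, 10.24 and 10.53 in WT and at 10.04, 10.47, 10.13 and 10.51 in KO. Less p53 activity stays open as well, with the list of p53 targets and growth arrest genes lower in KO (median -0.11, camera adjusted p = 0.0366). That list holds Cdkn2a itself, which was higher in KO. The shift had an adjusted p of 0.991 with an estimated correlation, and the interval of the median (-0.62 to 0.16) includes 0. No biological explanation by TTP was tested.

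Some arrays stood apart from their group by Dixon's test. Replicate 3 of WT at 30 min had a median of 8.55 (others 8.49 to 8.50), a 95th percentile of 10.35 (others 10.43 to 10.47) and a median correlation with its group of 0.971 (others 0.985 to 0.989). Replicate 3 of KO at 0 min had a Zfp36 signal of 9.28 (others 9.58 to 9.60), and replicate 5 of KO at 60 min a median correlation of 0.975 (others 0.988). Of 60 combinations of group and measure 5 stood apart, where chance gives about 3.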

How the results depend on the processing

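The alternatives with background subtraction, with each set of experiments alone, without 3 arrays, with KO times rescaled with lists among genes not lower in KO at 0 min, and with an estimated correlation on top of these list tests were chosen only after the result was seen. Of the values recomputed for named genes and lists over all alternatives, 11327 kept direction and side of the threshold, 494 fell short of it, 345 newly passed it and 6 reversed. The list of MAP kinase feedback genes reversed among genes not lower at 0 min (adjusted p = 0.896, or 0.971 with an estimated correlation as well), and 4 genes with experiments 4 and 5 alone: Il6 at 0 min to 0.46, Nes in WT to -0.13, Col3a1 at 120 min to 0.24 and Cxcl2 in KO to -0.028. Those of Il6 and Cxcl2 rest on 1 KO array at 0 min. Unless stated, the cause of a change in count was not tested. With scaling on ribosomal protein genes 1443 rose in WT, and 1381 rose and 5172 fell in KO, while 5606 rose in WT after median centring; each scaling moves all values of an array together. The replicate block gave 365 slower and 96 faster, 155 slower with KO not lower at 0 min, and 4217 higher in WT; of the values recomputed for named genes it newly passed 3 slope differences, 13 changes in WT, 14 in KO, 19 differences at 0 min and 19 at 120 min and ended 0, and it moved the list counts given beside the results. A block by experiment and line gave 594, 161 and 320, and 19 faster with KO not higher at 0 min, and array weights gave 307 slower. A filter at the 75th percentile tested fewer probe sets, with 1909 lower in KO over 120 min and 2209 lower in KO at 120 min, and no filter left 0 faster with KO not higher. Background subtraction left 19 faster and 1 with KO not higher, and KO times rescaled gave 121 slower and 40 with KO not lower. Experiments 1 to 3 alone gave 104 slower, 35 with KO not lower, and 1487 higher in WT, and experiments 4 and 5 alone gave 120, 43, 1 faster with KO not higher, and 827 higher in KO, with fewer arrays in each. Without the 3 arrays of lowest 95th percentile there were 364 slower, 136 with KO not lower and 8 faster with KO not higher. The difference of the 120 min changes gave 38 faster, 46 slower with KO not lower and 0 faster with KO not higher, and the slope over 30 to 120 min gave 63 slower, 31 faster, 16 and 0. Of the lists, 1 shifted up and 0 down with an estimated correlation, alone or on top of background subtraction, of rescaled KO times or of genes not lower at 0 min, 0 down with fry, which compares no list with other genes, and 2 up among genes not lower at 0 min and with KO times rescaled. Without 1 replicate, counts ranged from 80 to 261 slower, 40 to 50 faster, 32 to 99 slower with KO not lower, 0 to 4 faster with KO not higher, 1633 to 3069 higher and 3155 to 4086 lower in WT, 1767 to 3150 higher and 2430 to 2777 lower in KO, 2898 to 3568 higher and 2351 to 3192 lower at 0 min, 3841 to 5093 higher and 2625 to 3450 lower at 120 min, and 1 to 4 lists up and 0 to 1 down. The lowest counts came without replicate 1 (slower), 2 (faster; KO higher) and 4 (WT higher). Alternatives of an added offset were not run, because the values are already on the log scale. Signals near 8 limit what falls can be seen, so that slopes of dim transcripts are bounded by the background.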

Other observations

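Genes picked after their values were seen had high slope differences that were not past the threshold. They were Gadd45g (0.54 ± 0.20 log2 per h, adjusted p = 0.314), Ier5 (0.47 ± 0.17, adjusted p = 0.313), Gadd45b (0.37 ± 0.12, adjusted p = 0.141), Klf10 (0.36 ± 0.11, adjusted p = 0.117) and Tnfaip3 (0.34 ± 0.097, adjusted p = 0.0743). Each of the 5 was lower in KO at 0 min, from -0.42 for Ier5 to -1.37 for Gadd45g. Lif, which was higher in KO at 0 and 120 min, had a slope difference of 0.24 ± 0.10 (adjusted p = 0.408).

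Probe sets of a gene did not always share a call. Of the 156 genes called slower, 86 had another measured probe set that was not, and of these 144 probe sets 112 had a slope difference above 0. For 17 probe sets the slope difference was above 0 and past the threshold without a fall in WT, and for 6 it was below 0 without a fall in KO.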
